A study of Mus musculus with 8 samples.

How the data were processed

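Poly(A) RNA sequencing was analysed for 8 samples of sorted mouse pancreatic tumor cells, 4 from animals given vehicle and 4 from animals given trametinib and palbociclib (T/P). Groups and replicate numbers were taken from the sample titles. The labels describe the samples as separate replicates of each treatment and do not tie each one to an animal, so p-values measure the spread between these samples. No sequencing batch or date is named in the labels.

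The deposited values are raw read counts per Ensembl mouse gene, 1 column for each library, and they had not been normalized by the authors. Per the labels' protocols, TruSeq libraries were made from poly(A) RNA, single-end reads of 76 bases were obtained, adapters were removed with Trimmomatic and reads were aligned with STAR. The labels' protocols also name a human genome build, HTSeq and an RPKM matrix. Per the submitters' processing notes, the build was mm10 (GRCm38) and the tools were FastQC 0.11.5, Trimmomatic 0.36, STAR 2.5.3a and featureCounts 1.6.3. The deposited table holds mouse gene identifiers with whole-number counts and unequal column totals. Of the 53360 identifiers found in the mouse GENCODE M21 annotation, 51421 (96.37%) have the same start and end there, so the counts were treated as mouse GRCm38 counts. The strand setting, the rule for reads that map to several places and the annotation release are not given in the sources used here. Genes that overlap, have antisense partners or belong to families of near-identical copies are therefore uncertain. The deposited transcript length, in bases, was used only for a check of length.

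The table lists 53465 genes, of which 29027 had no count in any library. Column totals ran from 6236871 to 8118011 counts, which makes 3 counts equal to between 0.37 and 0.481 CPM (counts scaled to a common library size). Intervals made from counts cover counting error only, since reads were not tagged by molecule. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom between 1.945 and 8.783 over genes with at least 20 counts in the pair, and all 8 libraries were kept as separate replicates.

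Choices of test, gene lists and alternatives were fixed before the data were examined, except where a test is said to have been chosen later. In edgeR 4.0.16 (R 4.3.3), genes were filtered with filterByExpr at its minimum count of 10, scaled by TMM, and tested with the quasi-likelihood F test on a model with treatment as the only term. This left 12101 genes holding 99.76% of counts. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and a separate count required an absolute log2 fold change of at least 1, the size threshold that the series design names. Fold changes are T/P over Vehicle. Their 95% intervals use the total (residual and prior) degrees of freedom of the same fit. Group values are means of normalized CPM with the SD over 4 libraries. Library measures were compared with a two-sided exact permutation test, for which 4 against 4 samples allow no p below 0.02857.

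A total of 39 gene lists were fixed, 25 for pathways, 12 for other cell types and 2 for RNA quality. The 33 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided and adjusted over the lists. Calls were repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. Counts of changed members are given over all genes tested and, where different, adjusted over the list alone. In the other lists the 2 counts were equal.

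Named genes followed a rule with 4 parts. Part A took the 10 largest changes in each direction among called genes with a mean of at least 5 CPM, groups that did not overlap, and a symbol that is neither a predicted gene nor a pseudogene. Part B took up to 4 called members of smallest p in each pathway list, or the 2 of smallest p where fewer than 2 passed. Part C took the 2 most abundant members of each cell type or RNA quality list. Part D was a fixed set of drug targets, ERK and cell cycle genes, secreted factors, H2-K1, Kras and Trp53. The rule named 153 genes, and further members named beside their list's count were chosen after their values were seen.

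Alternatives were DESeq2 size factors, library totals alone, no filter on low counts, a stricter filter (a mean of at least 1 CPM and 10 counts in 4 libraries), the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, and 3 other forms of the list test (estimated correlation, fry and a prior count of 0.5). Added after seeing the data were a fit with the acinar marker score as a covariate and a fit without the matrix, fibroblast and acinar lists.

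The steps were tested on simulated counts for 12101 genes with the means and library sizes of T/P against Vehicle and 200 changed genes. The edgeR test recovered 74.67% of genes changed 1.5-fold, 89.33% of those changed 2-fold and 96% of those changed 4-fold, with 11 false calls among 11901 unchanged genes. In the data many more genes changed (4911), and changes of at least 2-fold were mostly upward (617 higher, 150 lower). The rates may therefore differ there. For 20 simulated lists of which 4 were shifted by 0.4 on the log2 scale, camera recovered 4 with 0 false calls. The simulated genes varied independently, so this does not test the lists against correlated genes.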

Results

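RNA was sequenced from tumor cells isolated from orthotopic pancreatic ductal adenocarcinomas in mice. The transplanted KPCmut cells carry an activated Kras allele and a mutant Trp53 allele and express luciferase and green fluorescent protein (GFP). They were grown in the pancreas of female C57BL/6 mice, and GFP-positive cells were sorted after 10 days of treatment. The mice received vehicle or, by mouth, trametinib at 1 mg/kg and palbociclib at 100 mg/kg, given 4 days on and 3 days off. Trametinib inhibits the kinases MEK1 and MEK2, which activate ERK, and palbociclib inhibits the cyclin-dependent kinases CDK4 and CDK6. The series title places the treatment in a study of senescence and vascular remodeling, and the comparison asks which transcripts differed in the tumor cells of treated animals. There were 4 libraries per group, with 6849401 to 8118011 counts in the Vehicle libraries and 6236871 to 8116007 in the T/P libraries. Totals were 7.58 ± 0.539 M counts (SD, n = 4) for Vehicle and 6.98 ± 0.845 M counts (SD, n = 4) for T/P (exact permutation p = 0.2571).

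Samples from treated animals had more transcripts of matrix genes and of Ccnd2, the gene of cyclin D2, and fewer of Dusp6, which encodes an ERK phosphatase, and of the keratin genes Krt6a and Krt18. Of 12101 genes tested, 4911 (40.6%) changed, 2484 higher and 2427 lower in T/P (edgeR quasi-likelihood test). Counts of changed members in the lists below are to be read against these shares. Most changes were small, with 84.4% of the changed genes under 2-fold. Among the 767 genes that changed at least 2-fold, 617 were higher and 150 lower. The groups did not overlap for 4507 genes (37.2%), where chance gives 2.86%. The main principal component held 68.6% of the variance and separated the groups, with Vehicle 4 lying nearest to the T/P libraries at -22.22 (the other Vehicle libraries were at -31.12 or below). Correlations of log2 CPM were 0.9857 to 0.99 within Vehicle, 0.9904 to 0.9928 within T/P and 0.9557 to 0.9697 between groups. Pancreatic acinar markers were also higher in T/P (camera adjusted p = 0.00244; adjusted p = 0.675 with an estimated correlation). When their mean (the acinar score) was entered as a covariate, an alternative chosen after seeing the data, 2844 genes changed. The score itself differs between the groups, and standard errors were a median of 1.57 times as large with it. For most genes discussed below that lost their call with it, the log2 fold change and SE are given without and with the score. For lists only the adjusted p is given. The acinar list, from which the score was made, also lost its call (camera adjusted p = 0.724). Without a filter on low counts, 1180 genes changed at least 2-fold.

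The largest increases included several genes of the extracellular matrix. Sfrp2, a secreted modulator of Wnt signaling on chromosome 3 (83766321 to 83774316, GRCm38), had 1 count over the Vehicle libraries and 362 over the T/P libraries, a ratio of 391 with a counting interval of 69.7 to 15500. Col10a1, a collagen of hypertrophic cartilage, rose from 5.59 ± 2.17 CPM to 135 ± 15.1 CPM (SD, n = 4 each; log2 fold change 4.57 ± 0.15 SE; edgeR adjusted p = 1.01e-11). Postn, which encodes the matrix protein periostin, rose from 4.196 ± 0.716 to 88.7 ± 16.7 CPM (log2 fold change 4.39 ± 0.16 SE; adjusted p = 3.36e-11). The others of the 10 largest increases were C1qtnf3, Aspn, Dpt, Lama2, Capn6, Lum and Mfap4, with log2 fold changes between 4.24 (Mfap4) and 6.25 (C1qtnf3).

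The largest decreases were smaller and included a keratin, an interleukin and a growth factor gene. Krt6a, a stress-induced keratin on chromosome 15 (101689932 to 101694307, GRCm38), fell from 86.4 ± 22.8 to 12.2 ± 1.28 CPM (SD, n = 4 each; log2 fold change -2.82 ± 0.17 SE; edgeR adjusted p = 5.82e-09). Ido1, which degrades tryptophan, fell 6.44-fold (adjusted p = 2.34e-05), Il10 fell 5.51-fold (1.52e-06) and Arg1, which degrades arginine, fell 4.27-fold (2.25e-09). Btc, a ligand of the epidermal growth factor receptor, fell 4.82-fold, and the Notch ligand Dll4 fell 4.16-fold. Dynap, Serpinb2 and Sh2d5 completed the group with log2 fold changes of -2.50, -2.30 and -2.18. Prl2c3 had a log2 fold change of -2.43, but it belongs to a family of near-identical prolactin-related genes and its count is uncertain.

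Genes switched on by RAS-ERK signaling were mostly lower in T/P, as a group and individually. Of 20 measured members, 14 fell, 2 rose and 4 did not pass the test, with a median log2 fold change of -0.39 (camera adjusted p = 0.000905; adjusted p = 0.166 with an estimated correlation). Dusp6, the ERK phosphatase on chromosome 10 (99263231 to 99267489), fell 2-fold, from 430.7 ± 29.1 to 215 ± 16.2 CPM (SD, n = 4 each; edgeR adjusted p = 2.43e-08). Dusp5 fell 2.57-fold, Epha4 fell 2.01-fold and Dusp4 fell 1.92-fold. Spry4, a feedback inhibitor of the pathway, had a log2 fold change of -0.34 (adjusted p = 0.0396), and its call was lost without Vehicle 3 (0.109), Vehicle 4 (0.0847), T/P 2 (0.121), T/P 3 (0.101) or T/P 4 (0.0771), with library totals alone (0.0515) and with the acinar score as a covariate (0.0661), where the log2 fold change was larger with a wider error (-0.34 ± 0.12 SE without, -0.498 ± 0.19 SE with the score). The members that rose were Spry1, another Sprouty inhibitor, at 1.09 and Myc at 0.36. Etv4 and Etv5, transcription factors induced by ERK, had values of -0.09 (adjusted p = 0.34) and 0.02 (0.871).

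The drug targets themselves and the G1 cyclin machinery moved in both directions. Of 15 measured members, 4 rose, 3 fell and 8 did not pass. Over all tested genes 40.6% changed, 2484 of 12101 higher and 2427 lower, so these counts do not set the list apart. The list was not called (camera adjusted p = 0.987; 0.0146 with fry, which compares no list with other genes), with a median log2 fold change of -0.06 and a mean of 0.07. Ccnd2, which encodes cyclin D2 (chromosome 6, 127125162 to 127152193), rose 2.73-fold, from 134.4 ± 6.2 to 366.3 ± 21.5 CPM (SD, n = 4 each; edgeR adjusted p = 1.47e-10). Ccne1, the gene of cyclin E1, rose 1.6-fold and Ccnd3 rose 1.28-fold. Ccnd1, the gene of cyclin D1, had 289 ± 27.7 CPM in Vehicle and 289.7 ± 15.1 CPM in T/P, with a 95% interval of the log2 fold change from -0.145 to 0.151. Map2k1, the gene of MEK1, fell 1.20-fold (adjusted p = 0.00221), whereas Map2k2, the gene of MEK2, had a log2 fold change of 0.19 (0.0169; 0.0523 without Vehicle 2, 0.0503 without Vehicle 4 and 0.0513 without T/P 1). Cdk6 had a log2 fold change of -0.20 (0.0337), a call lost without Vehicle 2 (0.0602), Vehicle 3 (0.0615), Vehicle 4 (0.0616), T/P 3 (0.0894) or T/P 4 (0.123), and Cdk4 had one of -0.02 (0.806). The log2 fold change was -0.05 for Kras (0.489) and -0.31 for Trp53 (0.00197). With the acinar score as a covariate the calls of Ccne1 (0.681 ± 0.17 SE without, 0.687 ± 0.28 SE with the score, adjusted p = 0.0947), Map2k2 (0.19 ± 0.058 and 0.167 ± 0.092, 0.208) and Cdk6 (-0.2 ± 0.071 and -0.184 ± 0.11, 0.254) were lost mainly through a wider error. The call of Trp53 (-0.313 ± 0.069 and -0.197 ± 0.1, 0.175) was lost with a smaller value as well.

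**Figure D1:**
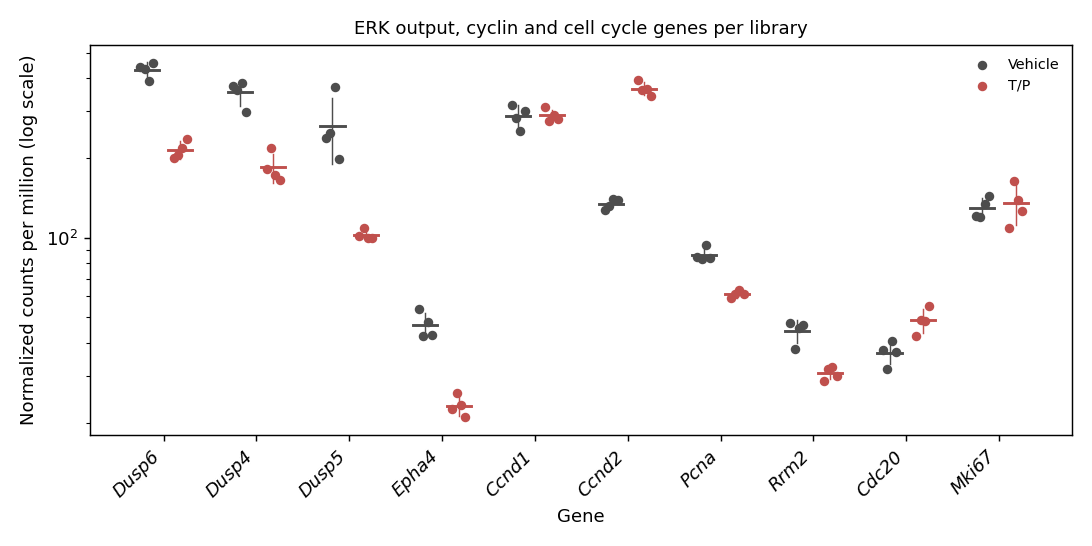
Normalized CPM (log axis) of 10 genes of ERK output, cyclins and the cell cycle in each of the 4 Vehicle (grey) and 4 T/P (red) libraries. Points are libraries, horizontal bars are means and vertical lines span 1 SD on either side. The groups do not overlap for Dusp6, which fell 2-fold, or for Ccnd2, which rose 2.73-fold, while those of Ccnd1 and Mki67 do.

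Genes of the G1/S transition and DNA replication were lower as a list, and genes of mitosis were not. Of 35 measured G1/S genes, 13 fell, 0 rose and 22 did not pass (median log2 fold change -0.15; camera adjusted p = 0.00835; adjusted p = 0.607 with an estimated correlation). E2f8, an E2F family transcription factor, fell 1.86-fold, from 20.6 ± 4.82 to 11.1 ± 0.637 CPM (SD, n = 4 each; edgeR adjusted p = 0.000227). Dut fell 1.57-fold, Rrm2, a subunit of ribonucleotide reductase, fell 1.44-fold, and Pcna, the sliding clamp of DNA polymerase, fell 1.41-fold. Of 31 measured G2/M genes, 10 rose, 1 (Anln) fell and 20 did not pass, with a median log2 fold change of 0.19 (camera adjusted p = 0.0343; adjusted p = 0.829 with an estimated correlation). That list call was also lost without Vehicle 2 (0.123), T/P 2 (0.201), T/P 3 (0.0683) or T/P 4 (0.0569) and with fry (0.25), and with the acinar score as a covariate the direction turned (0.966). Cdc20, an activator of the anaphase-promoting complex, rose 1.33-fold, from 36.8 ± 3.57 to 48.8 ± 5.21 CPM (edgeR adjusted p = 0.00205), and Foxm1 rose 1.21-fold. With the acinar score as a covariate both calls were lost, with smaller values and wider errors (Cdc20 0.407 ± 0.089 SE without, 0.211 ± 0.13 SE with the score, adjusted p = 0.253; Foxm1 0.277 ± 0.074 and 0.181 ± 0.12, 0.281). The proliferation marker Mki67 had 129.9 ± 11.4 CPM in Vehicle and 134.8 ± 23 CPM in T/P (log2 fold change 0.06, 95% interval -0.154 to 0.266; adjusted p = 0.679).

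Among inhibitors of cyclin-dependent kinases and genes linked to senescence, 9 of 17 measured members rose, 2 fell and 6 did not pass (10 and 2 adjusted over the list alone; camera adjusted p = 0.0327; adjusted p = 0.246 with an estimated correlation). The list call was lost without Vehicle 4 (0.0522) or T/P 3 (0.0513), with the acinar score as a covariate (0.103) and in a fit without the matrix, fibroblast and acinar genes (0.0676). Igfbp7, a secreted binding protein of insulin-like growth factors, rose 3.69-fold, from 35.3 ± 6.91 to 129.3 ± 34.7 CPM (SD, n = 4 each; edgeR adjusted p = 4.3e-07). Dcn, a matrix proteoglycan that is also in the fibroblast marker list, rose 2.58-fold, Ypel3 rose 1.44-fold, and Mmd fell 1.68-fold. Cdkn1a, the gene of p21, had a log2 fold change of 0.05 (95% interval -0.192 to 0.295; adjusted p = 0.748). Cdkn2b, the gene of p15, fell 1.15-fold (0.0121; 0.31 with the acinar score as a covariate, at -0.196 ± 0.057 SE without and -0.13 ± 0.088 SE with it), and Lmnb1, a lamin gene used as a senescence marker, had a value of -0.12 (0.244). Targets of p53 went both ways, with 5 rising and 4 falling of 20 measured (6 and 5 adjusted over the list alone; camera adjusted p = 0.977). These counts lie near the share of all tested genes that changed (40.6%, with 2484 higher and 2427 lower of 12101). Sesn2 rose 1.5-fold and Btg2 1.39-fold, while Perp fell 1.73-fold and Pmaip1 fell 1.4-fold.

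Secreted factors of the senescence-associated secretory phenotype did not move as a block. Of 26 measured cytokine and chemokine genes, 6 rose, 6 fell and 14 did not pass (camera adjusted p = 0.787). Cxcl12, a chemokine of stromal cells, rose 3.07-fold, from 246.4 ± 16.8 to 756.1 ± 82.6 CPM (SD, n = 4 each; edgeR adjusted p = 8.22e-10), and Csf1, the macrophage growth factor, rose 1.95-fold. Il33 fell 2.38-fold, Ccl2, a chemoattractant of monocytes, fell 1.66-fold and Cx3cl1 fell 1.51-fold. Il6 had 7.32 ± 3.32 CPM in Vehicle and 6.47 ± 1.13 CPM in T/P (adjusted p = 0.671). Ccl5, at 1.46 ± 0.467 and 2.64 ± 0.704 CPM, had a log2 fold change of 0.82 (adjusted p = 0.0397) that lost its call without Vehicle 1 (0.0922), Vehicle 3 (0.0535), Vehicle 4 (0.105), T/P 1 (0.114), T/P 2 (0.05) or T/P 4 (0.107) and with DESeq2 (0.119) or no filter on low counts (0.0524). Of 27 measured proteases and their inhibitors, 12 rose, 7 fell and 8 did not pass (12 and 8 adjusted over the list alone; camera adjusted p = 0.502). Timp3, an inhibitor of metalloproteinases, rose 12.4-fold, from 12.9 ± 1.96 to 158.4 ± 56 CPM (edgeR adjusted p = 1.26e-08). Serpine2 rose 6-fold and Mmp2 rose 1.99-fold, while Plau, the urokinase gene, fell 1.57-fold. Whether tumor cells or host cells were the source of Cxcl12, Timp3, Serpine2 and Mmp2, or of Igfbp7 above, was not tested. Mmp3 had a log2 fold change of 0.63 (0.0287), a call lost without Vehicle 1 (0.064), Vehicle 2 (0.0848), Vehicle 3 (0.0703), T/P 2 (0.0561), T/P 3 (0.0995) or T/P 4 (0.0617), with DESeq2 (0.158) and with the acinar score as a covariate (0.619, at 0.63 ± 0.21 SE without and 0.266 ± 0.35 SE with it). Without Vehicle 4 its log2 fold change was 0.96.

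Pro-angiogenic and growth factor genes also moved in both directions, with 8 rising, 14 falling and 11 not passing of 33 measured (camera adjusted p = 0.428). Vegfa, the main endothelial growth factor, had 425.6 ± 33.5 CPM in Vehicle and 396.2 ± 32.2 CPM in T/P (SD, n = 4 each; log2 fold change -0.10, 95% interval -0.256 to 0.0491; edgeR adjusted p = 0.269). Tgfb3 rose 1.89-fold, Pdgfc 1.56-fold and Fgf2 1.49-fold. Areg, a ligand of the epidermal growth factor receptor, fell 3.37-fold, Adm fell 2.54-fold and Pdgfa fell 1.48-fold. Pdgfb had a log2 fold change of -0.32 (0.0209), a call lost without Vehicle 2 (0.0748), Vehicle 3 (0.0614), T/P 1 (0.0507) or T/P 2 (0.0679). The calls of Pdgfb (-0.322 ± 0.1 SE without, -0.271 ± 0.16 SE with the score, adjusted p = 0.239) and Fgf2 (0.572 ± 0.16 and 0.641 ± 0.26, 0.0871) were lost with the acinar score as a covariate, mainly through a wider error. Of 12 measured anti-angiogenic factors, 7 rose and 2 fell (Flt1 and Spry4), with a median log2 fold change of 0.55. As many as 3 of these members are shared with other lists, among them Timp3 (proteases and inhibitors) and Spry4 (ERK output). That list just missed the threshold (camera adjusted p = 0.0522; 0.257 with an estimated correlation) and passed it without Vehicle 1 (0.042), Vehicle 4 (0.0435) or T/P 2 (0.0292), without a filter on low counts (0.0251) and with fry (0.000198). Sema3f, a semaphorin, rose 6.71-fold and Serpinf1, the gene of pigment epithelium-derived factor, rose 3.47-fold, while Flt1, a receptor of VEGF, fell 1.5-fold. The source of Sema3f and Serpinf1, tumor cells or host cells, was not tested either. Of 14 measured adhesion molecules and leukocyte ligands, 2 rose and 4 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.369). Mcam rose 1.67-fold, while Alcam fell 1.47-fold, Cd44 fell 1.39-fold and Ulbp1, a ligand of a natural killer cell receptor, fell 1.27-fold.

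Antigen presentation and interferon genes were not called as groups. Of 20 measured MHC class I genes, 5 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.263), and of 28 measured interferon-stimulated genes, 5 fell and 0 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.206). Both lists were called lower without Vehicle 4, at 0.00489 and 0.00421. B2m, the light chain of MHC class I, fell 1.41-fold, from 869.6 ± 258 to 614.7 ± 52.4 CPM (SD, n = 4 each; edgeR adjusted p = 0.0138; 0.0705 with DESeq2). Without 1 of the libraries its log2 fold change of -0.50 ran from -0.65 to -0.30, the smallest size being without Vehicle 3. H2-K1 had a log2 fold change of -0.18 (0.512), which was -0.39 (0.0185) without Vehicle 4 and 0.0803 (0.723) without Vehicle 3, and it passed without a filter on low counts (0.0206). The interferon-induced chemokine gene Cxcl10 had one of -0.39 (0.218), which was -0.61 (0.0103) without Vehicle 4, -0.26 without Vehicle 2 and -0.13 without Vehicle 3. It passed without a filter on low counts (4.88e-05). The groups of both genes overlapped, however. Cxcl10 ran from 21.89 to 64.04 CPM in Vehicle and from 28.19 to 38.03 CPM in T/P. H2-K1 ran from 189.7 to 518.4 CPM in Vehicle and from 272.9 to 328 CPM in T/P. The main test called neither gene, and their passing values without a filter are therefore not read as a change. The groups of B2m above and Stat1 below, which the main test called, overlapped as well. Vehicle 4 held 601.3 CPM of B2m and 17.74 CPM of Stat1. The T/P libraries ran from 567.5 to 662.9 CPM for B2m and from 16.97 to 25.09 CPM for Stat1. Ifitm3, an interferon-induced membrane protein, fell 1.45-fold (7.44e-05). Stat1 fell 1.47-fold (0.045), a call lost without Vehicle 2 (0.106), Vehicle 3 (0.156), T/P 2 (0.126), T/P 3 (0.104) or T/P 4 (0.0749), with DESeq2 (0.16) or limma-voom (0.0902) and with the acinar score as a covariate (0.166), where the value was no smaller but its error wider (-0.555 ± 0.21 SE without, -0.623 ± 0.31 SE with the score). Without Vehicle 3 its log2 fold change of -0.55 was -0.33. Of 20 measured genes of the NF-kappa B pathway, 1 fell, Nfkb1 by 1.22-fold (0.00317; 0.141 with the acinar score as a covariate, at -0.284 ± 0.067 SE without and -0.215 ± 0.1 SE with it), and 0 rose (camera adjusted p = 0.502).

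Matrix genes rose together, as did fibroblast markers, and of the 33 lists tested matrix genes were the only list called with both the preset and the estimated correlation. Of 25 measured members, 20 rose, 0 fell and 5 did not pass, with a median log2 fold change of 1.12 (camera adjusted p = 5.1e-14; adjusted p = 0.0426 with an estimated correlation). Col3a1 (chromosome 1, 45311538 to 45349706) rose 4.76-fold, from 1944 ± 85.6 to 9256 ± 669 CPM (SD, n = 4 each; edgeR adjusted p = 7.12e-12). Col12a1 rose 5.29-fold and the proteoglycan gene Bgn rose 4.31-fold. Col1a1 (chromosome 11, 94936224 to 94953042) rose 13.5-fold, from 391.8 ± 134 to 5306 ± 231 CPM (5.2e-10). Epithelial genes were lower, with 5 of 8 measured members falling and 3 not passing (median log2 fold change -0.85; camera adjusted p = 0.0275; adjusted p = 0.261 with an estimated correlation and 0.826 without a filter on low counts). Krt18 fell 2.61-fold, from 974.5 ± 127 to 373.3 ± 14.4 CPM, Cdh1, the gene of E-cadherin, fell 2.26-fold and Krt8 fell 1.84-fold. Of 18 measured genes of epithelial-mesenchymal transition, 5 rose and 3 fell (camera adjusted p = 0.502; 0.0142 with fry). Acta2, the smooth muscle actin gene, rose 4.01-fold, Snai2 1.44-fold and Cdh2 1.43-fold. With the acinar score as a covariate the call of Snai2 was lost mainly through a wider error (0.526 ± 0.14 SE without, 0.469 ± 0.23 SE with the score, adjusted p = 0.159) and that of Cdh2 mainly through a smaller value (0.518 ± 0.093 and 0.263 ± 0.12, 0.13). Of 6 measured ductal and progenitor genes, 2 fell, Foxa2 by 2.24-fold and Sox9 by 1.62-fold, and 0 rose (camera adjusted p = 0.282; 0.0282 with fry).

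**Figure D2:**
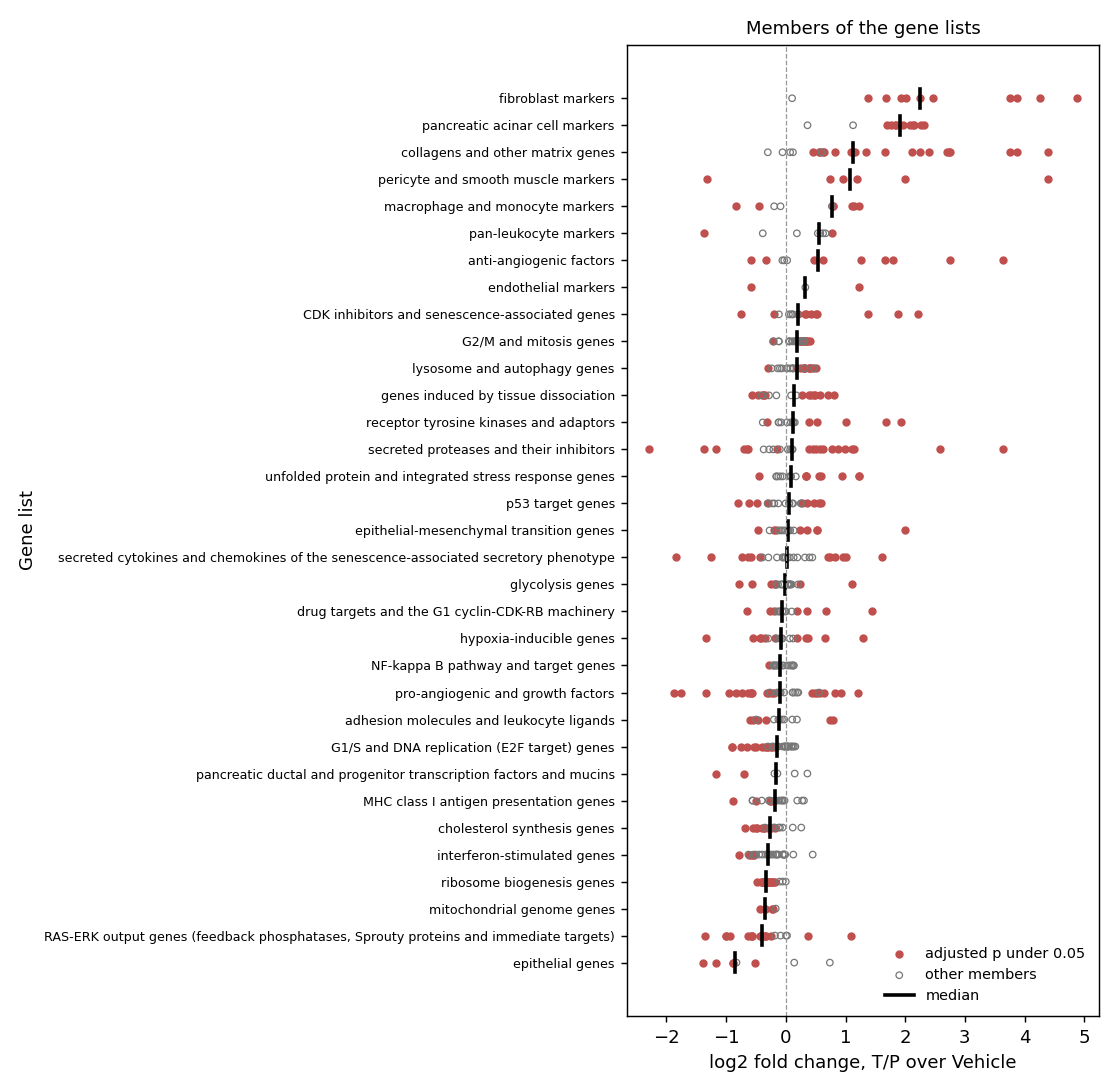
log2 fold changes (T/P over Vehicle, horizontal axis) of the tested members of the 33 gene lists with at least 3 tested members (vertical axis, ordered by median). Filled points are members with an adjusted p under 0.05, open circles are other members and black bars are list medians. Fibroblast markers have the highest median, 2.25, and epithelial genes the lowest, -0.85.

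Genes of ribosome biogenesis fell together by small amounts, with 22 of 25 measured members lower, 0 higher and a median log2 fold change of -0.33 (camera adjusted p = 1.34e-07; adjusted p = 0.246 with an estimated correlation). Noc4l fell 1.39-fold, from 47.01 ± 2.24 to 33.8 ± 2.18 CPM (SD, n = 4 each; edgeR adjusted p = 8.91e-05), Nop58 fell 1.34-fold and Nop56 fell 1.28-fold. Of 20 measured genes of cholesterol synthesis, 11 fell and 0 rose (camera adjusted p = 0.00118; adjusted p = 0.592 with an estimated correlation). Nsdhl fell 1.6-fold and Fdft1, the squalene synthase gene, fell 1.47-fold. Of 25 measured lysosome and autophagy genes, 11 rose and 1 fell (camera adjusted p = 0.0157; adjusted p = 0.56 with an estimated correlation), with Hexa rising 1.42-fold and Psap rising 1.32-fold. Of 20 measured genes of the unfolded protein and integrated stress responses, 8 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0708; 0.644 with an estimated correlation, 0.0313 without Vehicle 3 and 0.007 with fry). Herpud1 rose 2.35-fold and Trib3 rose 2.34-fold. Of 15 measured receptor tyrosine kinases and adaptors, 5 rose and 1 fell (camera adjusted p = 0.146, and 0.00029 with fry). Pdgfrb rose 3.81-fold and Pdgfra rose 3.2-fold. Both are also members of the fibroblast marker list, and the tests run here cannot tell host fibroblasts from tumor cells as their source. Glycolysis genes (2 higher, 5 lower of 20; camera adjusted p = 0.598) and hypoxia-inducible genes (5 higher, 6 lower of 20; camera adjusted p = 0.641) moved in both directions. The glucose transporter genes Slc2a3 and Slc2a1 fell 1.73-fold and 1.48-fold, while Eno2 rose 2.16-fold and Car9 rose 2.45-fold.

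Markers of several other cell types moved with the treatment. Of 11 measured fibroblast markers, 10 rose and 0 fell, with a median log2 fold change of 2.25 (camera adjusted p = 6.96e-09; adjusted p = 0.166 with an estimated correlation). The list shares 6 of these members with other lists, Col1a1 and Col3a1 among them. Of 12 measured acinar markers, 10 rose and 0 fell (median log2 fold change 1.91; camera adjusted p = 0.00244; adjusted p = 0.675 with an estimated correlation). Ctrb1, which encodes the digestive enzyme chymotrypsinogen, rose from 34.9 ± 24.4 to 168.7 ± 65.2 CPM (SD, n = 4 each; edgeR adjusted p = 8.23e-05), and Cel rose 4.82-fold. All 6 measured pericyte and smooth muscle markers changed, 5 rising and Rgs5 falling 2.49-fold (camera adjusted p = 0.0163; adjusted p = 0.246 with an estimated correlation). Macrophage markers had 5 of 10 rising and 2 falling (6 and 2 adjusted over the list alone; camera adjusted p = 0.304), with Lyz2 rising from 5.97 ± 1.63 to 13.2 ± 2.18 CPM. Pan-leukocyte markers had 1 rising and 1 falling of 8 (camera adjusted p = 0.449), Cd53 falling 2.58-fold, and endothelial markers had 1 rising (Plvap) and 1 falling (Flt1) of 3 (camera adjusted p = 0.977). Lists with fewer than 3 measured members were not tested. Among these, Lcn2 of the neutrophil list rose from 0.551 ± 0.35 to 3.06 ± 1.3 CPM, and the mesothelial markers Msln and Bnc1 fell 1.27-fold and 1.63-fold. With the acinar score as a covariate the calls of Lcn2 (2.5 ± 0.43 SE without, 1.69 ± 0.68 SE with the score, adjusted p = 0.0877), Msln (-0.345 ± 0.059 and -0.255 ± 0.09, 0.0534) and Cel, itself part of that score (2.27 ± 0.37 and 0.594 ± 0.23, 0.0785), were lost. Of the T and natural killer cell markers, Trbc2 rose from 2.82 ± 1.47 to 5.19 ± 1.69 CPM (edgeR adjusted p = 0.0367), a call lost without Vehicle 1 (0.107), Vehicle 2 (0.0929), T/P 1 (0.11) or T/P 3 (0.114), with DESeq2 (0.051) and with the acinar score as a covariate (0.526, at 0.907 ± 0.33 SE without and 0.484 ± 0.51 SE with it). Trac had 2.38 ± 0.913 CPM in Vehicle and 2.57 ± 0.412 CPM in T/P. Ighm had 2.06 ± 2.11 and 2.23 ± 1.4 CPM, Hbb-bs had 2.30 ± 0.948 and 3.14 ± 1.06 CPM, and 0 endocrine markers passed the filter on low counts.

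The hosts were female, and the libraries held transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty as well as Xist. Xist, transcribed from the inactive X chromosome of female cells, had 48 counts over the Vehicle libraries (3 to 24 per library) and 58 over the T/P libraries (7 to 21 per library). Its level was 1.56 ± 1.37 CPM in Vehicle and 2.04 ± 0.644 CPM in T/P (SD, n = 4 each; exact permutation p = 0.6). Ddx3y had 28.2 ± 2.7 and 23.8 ± 5.43 CPM (exact permutation p = 0.229). The other Y-linked genes also had lower means in T/P, with Eif2s3y at 17.7 ± 2.63 and 15.6 ± 2.03 CPM (exact permutation p = 0.257). Kdm5d had 14.8 ± 0.623 and 14 ± 1.99 CPM (0.486), and Uty had 8.87 ± 2.5 and 6.56 ± 1.28 CPM (0.171). Mitochondrial transcripts took 1.09 ± 0.12% of counts in Vehicle and 0.864 ± 0.0521% in T/P (SD, n = 4 each; exact permutation p = 0.02857, the smallest that 4 against 4 samples allow). Of 7 measured mitochondrial genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.0163; adjusted p = 0.644 with an estimated correlation), with mt-Co1 falling 1.35-fold. Genes induced by tissue dissociation had 8 rising and 5 falling of 18 (camera adjusted p = 0.563), with Fos rising 1.4-fold and Egr1 falling 1.47-fold. The 10 most abundant genes took 5.746 ± 0.0669% of counts in Vehicle and 6.246 ± 0.0654% in T/P (exact permutation p = 0.02857).

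**Figure D3:**
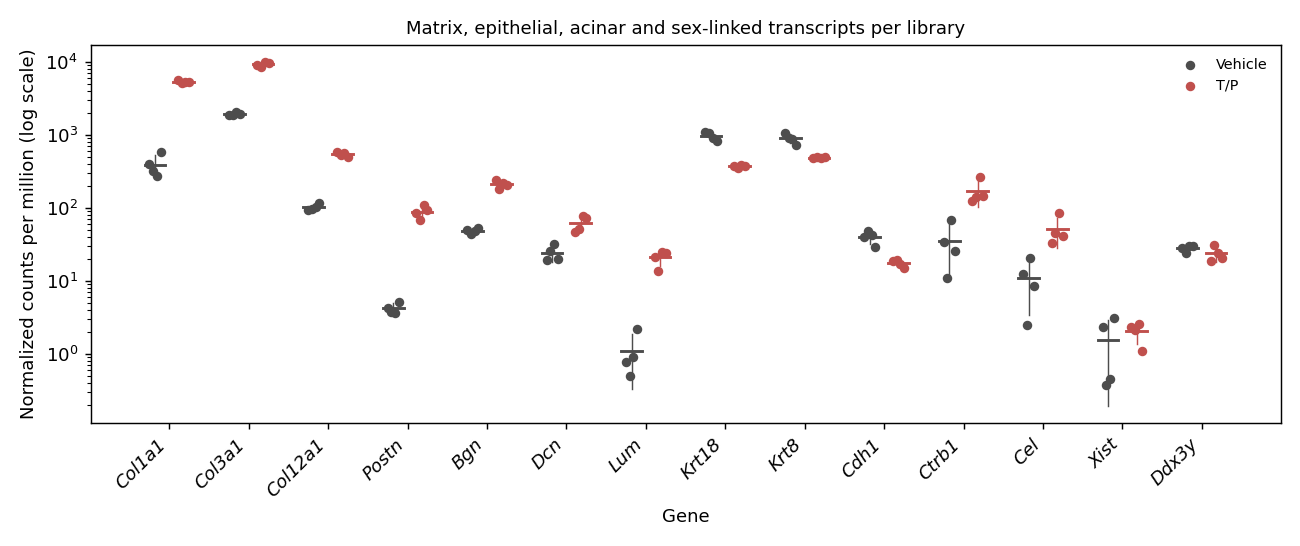
Normalized CPM (log axis) of matrix, epithelial, acinar and sex-linked transcripts in each of the 4 Vehicle (grey) and 4 T/P (red) libraries. Points are libraries, horizontal bars are means and vertical lines span 1 SD on either side. Col1a1 rose 13.5-fold without overlap of the groups, while Xist, at 1.56 CPM in Vehicle and 2.04 CPM in T/P, overlaps.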

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

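Apart from the check of gene length, the tests of explanations below were chosen after the result they bear on was seen. Each group of 4 libraries was searched for a library lying far from the others (a gap above 0.829 of the range) in the named genes, the library measures and the mean of each gene list. Of 380 such groups, 19 held one, which is no more than the roughly 5% that chance alone gives. The libraries below are therefore listed for description only.

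In the Vehicle group, Sfrp2 had its only count in Vehicle 3 (0.15 CPM, others 0), Pcna was highest in Vehicle 3 (94.19 CPM, others 83 to 84.28) and Msmo1 was highest there too (178.8 CPM, others 147.3 to 151.1), as was the mean of the cholesterol synthesis genes (6.024 on the log2 scale, others 5.828 to 5.861). Vehicle 1 lay apart for Il33 (126.8 CPM, others 167.3 to 173.7), Krt19 (319.7 CPM, others 223 to 230.7), Trib3 (8.144 CPM, others 7.104 to 7.199) and the mean of the glycolysis genes (8.509, others 8.354 to 8.373). Vehicle 4 lay apart for Csf1 (68.63 CPM, others 72.89 to 72.91) and Ulbp1 (77.18 CPM, others 62.94 to 63.74).

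In the T/P group, T/P 3 lay apart for Serpinb2 (1.232 CPM, others 2.664 to 2.805), Ulbp1 (57.28 CPM, others 50.65 to 51.65), Ctrb1 (265.8 CPM, others 125.3 to 143.6) and mt-Cytb (2591 CPM, others 2229 to 2272). T/P 1 lay apart for Fdft1 (52.21 CPM, others 57.4 to 58.19) and for the means of the ERK output genes (6.921, others 6.818 to 6.834) and the G1/S genes (4.805, others 4.885 to 4.899). Foxm1 was highest in T/P 2 (101 CPM, others 81.94 to 85.12) and Nop58 lowest in T/P 4 (104.6 CPM, others 115.2 to 117.2).

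The counts of changed genes were highest in the real grouping, and the count of changed lists was not. The 8 libraries can be split into 4 and 4 in 35 ways. The real split alone had as many changed genes (4911 against at most 0 in another split by the edgeR test). It was also the only 1 with as many changed at least 2-fold (767 against at most 0). Ranking highest of the 35 makes chance an unlikely source of these counts and is the most that this test can show. Every other split mixes Vehicle and T/P libraries, which widens the spread within its groups. The 0 calls there therefore do not measure what chance alone would give. Another split reached 1497 genes at an unadjusted p under 0.05, against 5876 in the real one. For the lists, 3 of the 35 splits called as many, with 13 in the real split and up to 14 in another, so chance cannot be excluded for the number of lists called with a preset correlation.

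The rise of matrix and fibroblast-marker genes was weighed against host fibroblasts carried through the GFP sort and against gene length. The ratio of Xist, a mark of female host cells, had an edgeR interval of 0.823 to 2.01, below the median rise of the fibroblast markers, 4.76-fold, but Vehicle libraries held 3 to 24 counts, and an exact permutation interval that carries this spread, chosen after the edgeR one was seen, reaches 6.82, so Xist cannot tell whether host fibroblasts increased. The gains in absolute terms were 37.99 CPM for Dcn, 20.06 CPM for Lum and 4914 CPM for Col1a1, which exclude neither source because the profile of any host fibroblasts is not known. Random sets of genes matched on transcript length and expression had a median log2 fold change of 0.00217 against 1.12 for the matrix list, and 0 of 10000 sets reached it, so gene length does not account for the rise. More host fibroblasts and expression by the tumor cells under treatment both stay open, and the tests run here cannot tell them apart. The genes did not all vary alike over T/P 1 to 4. Dcn had 47.38, 51.89, 77.11 and 72.86 CPM there, while Col1a1 had 5613, 5057, 5303 and 5250 CPM. Whether they rose from 1 source was not tested, and the Y-linked genes were not weighed.

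The acinar transcripts rose by 335 CPM in all (0.0335% of counts), and their deviations from the group means moved together over the libraries, with a mean correlation of 0.909 among 12 genes, where random sets matched on expression had a median of -0.00429 and a 95% range reaching up to 0.135. This is consistent with RNA from acinar cells entering the libraries in varying amounts from 1 source, although genes regulated together would give the same correlation. The Xist ratio was 1.29, with an upper bound of 2.01 by edgeR, below the median acinar rise of 3.75-fold, and of 6.82 by permutation, above it. So small a gain might also add too little Xist to be seen, which was not measured. Whole acinar cells and free RNA therefore cannot be told apart (the permutation bound and the condition on the gain were both added after the ratio was known). A direct effect of the treatment on the tumor cells was not tested and stays open.

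The absence of a fall in G2/M genes under a CDK4/6 inhibitor was weighed against low counts and against scaling. Of the 31 genes, 0 had a 95% interval that includes a log2 fold change of -1, which excludes too few counts to see a fall by that size, and the lowest bound was -0.438. The median log2 fold change was 0.194 at its lowest over 4 scalings (TMM, DESeq2 size factors, library totals, and TMM without the matrix, fibroblast and acinar genes), but these moved the median of all genes only from -0.00477 to 0.00629, too little to test scaling, which stays open (this condition was added after the median, at first read as excluding scaling, was known). The time between the last dose and sampling is not given in the sources used here. In the same libraries 14 of 20 ERK output genes fell and 2 rose, and 13 of 35 G1/S genes fell and 0 rose. Differences between the groups were thus still present in these genes at sampling, although both list calls were lost with an estimated correlation (camera adjusted p = 0.166 and 0.607). Whether the drugs were still acting then was not tested. A drug effect that had passed by then, on the G2/M genes or more widely, stays open.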

How the results depend on the processing

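The fits with the acinar marker score and without the matrix, fibroblast and acinar lists were chosen after seeing the data. Shared calls had 0 opposite signs in any of the alternatives. Leaving out each library gave 4209 to 5127 changed genes (774 to 887 at least 2-fold) and 11 to 15 lists, and the replicate number as a block gave 4753 genes. Deviations of same-numbered libraries from their group means were weakly correlated (-0.019, 0.0441, 0.104 and -0.0586), with 2 of 4 best matched to their own number. These values were not tested. They give no clear sign that the numbers pair samples and cannot exclude it. With the block, Cdk6 (0.0596), Ccl5 (0.0646), Stat1 (0.0542) and Ifit3 (0.0552) were not called and the anti-angiogenic list was (0.0484). Over the other alternatives except the acinar score, 4284 to 5190 genes changed, keeping 82.9% to 99.6% of the calls, and fry called 18 lists. The main counts moved by over 1.5 times in 3 settings. Without a filter on low counts, where 24438 genes were tested, 1180 genes changed at least 2-fold, 956 of them upward. With the acinar score as a covariate, which itself differs between the groups, 2844 genes changed, 1440 higher and 1404 lower. With an estimated correlation 1 list was called.

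Directions turned only for results that had not been called in the main test, apart from the G2/M list, and the cause was not tested. For adjusted p of lists, the drug targets gave 0.814 without a filter and 0.978 with the replicate block, p53 targets 0.826 without a filter and 0.724 with the acinar score, the ductal and progenitor list 0.688 without a filter, endothelial markers 0.893 with the acinar score and 0.517 with fry, hypoxia 0.992 with fry and G2/M genes 0.966 with the acinar score. For log2 fold changes, the acinar score gave -1.18 for Ighm, -0.0055 for Arhgdib, -0.14 for Mki67 and -0.27 for Cdkn1a, and Ccnd1 had -0.013 without a filter and -0.0086 with DESeq2.

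Leaving out each library turned the direction in at least 1 case for these uncalled results. The adjusted p ran from 0.458 to 0.965 for cytokines, 0.821 to 0.994 for endothelial markers, 0.869 to 0.976 for drug targets, 0.753 to 0.996 for p53 targets. The log2 fold change ran from -0.074 to 0.36 for Trac, -0.23 to 0.86 for Ighm, -0.061 to 0.012 for Cdk4, -0.058 to 0.045 for Ccnd1, -0.052 to 0.14 for Mki67, -0.024 to 0.16 for Cdkn1a, -0.33 to 0.16 for Il6, -0.39 to 0.0803 for H2-K1.

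Genes near the floor are limited by depth, since 3 counts equal 0.37 to 0.481 CPM.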

Other observations

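The terms and genes in this part were chosen after the data were seen, while the tests of other splits and of further Wnt targets were set down before they were run. Over the GO terms that the deposited table gives, 2537 with 10 to 200 tested genes, 164 passed camera with a preset correlation and 0 with an estimated one (153 at an unadjusted p under 0.05). A total of 2 of the 35 splits of the libraries called as many (168 in the other), so chance cannot be excluded for that number and the counts below are descriptive. Structural genes of the cytosolic large ribosomal subunit were lower in 42 of 56 cases and higher in 0, with a median log2 fold change of -0.31, for example Rpl30 (-0.52 ± 0.07 SE, edgeR adjusted p = 2.16e-05) and Rpl39 (-0.59 ± 0.08 SE, adjusted p = 2.24e-05). In the proteasome core complex 13 of 19 genes fell and 0 rose, including Psma1 (-0.44, adjusted p = 5.29e-05) and Psmb7 (-0.42, adjusted p = 0.000134). In amino acid transport 15 of 24 genes rose and 0 fell, including the cationic amino acid transporter Slc7a2, which went from 17.95 ± 2.54 to 70.19 ± 7.88 CPM (SD, n = 4 each; adjusted p = 1.87e-09), and the neutral amino acid transporter Slc7a5 (0.51, adjusted p = 9.48e-05).

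Genes that restrain canonical Wnt signaling were higher more often than lower, with 40 rising and 10 falling of 80 tested in that GO term (camera adjusted p = 0.000381; adjusted p = 0.755 with an estimated correlation). Axin2, a feedback inhibitor switched on by the pathway, went from 1.77 ± 0.369 to 12.0 ± 2.42 CPM (SD, n = 4 each; log2 fold change 2.74, edgeR adjusted p = 8.93e-08), Nkd2 had a log2 fold change of 2.77 (3.14e-05) and the Wnt-responsive transcription factor Lef1 one of 2.22 (7.7e-06). A candidate explanation is a rise of canonical Wnt target genes at large. Of 20 further target genes, listed after Axin2, Nkd2 and Lef1 were seen and before their own values were, 8 were tested. Among these 8, 5 rose (Bmp4, Notum, Kremen1, Lgr5 and Znrf3) and 2 fell (Tcf7 and Dkk2), with a median log2 fold change of 0.32. The result meets the bound set for the hypothesis, but 8 genes cannot settle it. The listed targets that were not tested are not covered. Whether the 8 genes belong to the GO term above was not checked, so they may not be independent of it. Some of these genes are also expressed by stromal cells, so a source outside the tumor cells stays open.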
